A study of Prunus avium with 340 samples.

How the data were processed

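RNA was extracted from flower buds and libraries were prepared with a stranded mRNA kit, per the labels' protocols. The deposited values are whole-number read counts per gene, not normalised, 1 file per sequencing lane in the deprivation series and per library in the exposure series. Per the submitters' processing notes, Trimmomatic 0.36, STAR and HTSeq were used; the versions of the last 2, the genome build and the strand setting of the counting are not given in the sources used here. The files held 48133 gene models and 5 HTSeq summary rows, which were kept out of library sizes and tests. As shares of all counts in the files, summary rows included, reads with more than 1 alignment came to a median of 11.7% in the deprivation series and 5.79% in the exposure series. Ambiguous reads came to 3.39% and 3.00%, and reads outside genes to 0.48% and 0.56%.

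The 340 deposited samples came from 162 libraries. The 3 lanes of each deprivation library differed by little more than counting noise (chi-square per degree of freedom 1.17 to 1.45). They were summed, so that a library is 1 replicate. Biological replicates gave at least 2.1 on whole libraries, and as this value grows with depth the 2 are not on the same scale. Groups and replicate numbers come from the sample titles. The series design text gives another season for the exposure series than the titles and names a January date that no sample analysed here carries; the titles were used. None of the identifiers (0 matched) could be looked up in the reference table of 37283 genes, so the functional gene lists fixed before the data were examined are void. Genes are named by a rule also fixed before: per comparison, the 2 called genes with the largest rise and the 2 with the largest fall, with a mean of at least 5 CPM over the compared libraries and, in comparisons of arms, the same sign at every averaged date. The text prints those of the main comparisons, and values of these genes elsewhere.

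Each series was fitted on its own with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM factors, robust quasi-likelihood fit, 1 coefficient per arm and date), with Benjamini-Hochberg adjustment over the genes of a contrast and calls at an adjusted p under 0.05. A comparison of arms is the mean over their shared dates with equal weights. CC of 31 May 2019 was sequenced on flow cells of its own, so that date is left out of the CC2MAR comparison; there the flow cell and the arm cannot be told apart. In the exposure series 4 libraries came from a second flow cell. Seasonal sets hold the 500 called genes with the largest winter-versus-late-summer or spring-versus-winter change of at least 1 log2 unit in the Control buds of a series, and were tested only in the other series with camera in limma 3.58.1 (log2 CPM with a prior count of 2, preset correlation 0.01), adjusted over the 4 sets of a contrast, and again with an estimated correlation and fry. Within a series the 4 sets share genes: 190 genes are both winter-high and spring-low in the deprivation series. Set levels are means of log2 CPM minus the mean of the late-summer Control groups; at single dates they are given with no test. For the closest Control date, both series were first centred on their own Control buds, as the median absolute log2 difference between the August Controls of the 2 series was 0.287, against a median SD between replicates of 0.168.

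Alternatives were DESeq2 1.42.0, RLE factors, no filter, a replicate block, each replicate number left out, the compared groups alone, 1 lane per library, flow cell as a covariate, each date left out and a minimum change of 1 log2 unit, with 200 or 1000 genes per seasonal set, and 500 or 5000 genes or the Pearson correlation for the closest date. All were fixed before the data were examined except leaving out the second flow cells, single spring dates of the exposure series, the uncentred and same-series closest dates, and fry and RLE for the seasonal sets. Leaving out a replicate number leaves some groups with 1 library, which is then assumed to vary like the others. The scripts were tested on simulated data with 200 changed genes of at least 5 CPM on average, each with the same mean at all dates. For CC versus Control over 24885 genes, edgeR recovered 97.0% of genes changed by 0.5 log2 units and 100.0% of those changed by 1 or 2, with 10 false calls. For Cold_July versus Control over 26243 genes it recovered 91.0% and 100.0%, with 11 false calls. Recovery of weaker genes, with changes over dates or with as many changed genes as were called in the data, was not tested.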

Results

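Flower buds of the sweet cherry (Prunus avium) cultivar Regina were profiled by RNA sequencing on adult potted trees, in a cold-deprivation series sampled from July 2018 to May 2019 and a cold-exposure series sampled, by its sample titles, from summer to March 2023. The deprivation series held 89 libraries in 31 groups of an arm and a date, 4 of which had 2 libraries and the others 3. Its arms are labelled Control, CC, CC2NOV, CC2JAN and CC2MAR. The exposure series held 73 libraries in 25 groups, 2 of which had 2 libraries, with arms labelled Control, Cold_July, Cold_August, Cold_July_Field and Cold_August_Field. The labels give no temperatures and do not spell out the arm names, so the names are used as they stand. Reads counted in genes ranged from 6.69 to 21.2 M per library in the deprivation series (median 11.3) and from 8.97 to 61.4 M in the exposure series (median 22.4). Replicates are described as separate buds and the labels do not say whether they came from separate trees, so p-values measure the spread between these samples. The lowest Spearman correlation between replicates of a group was 0.963 and 0.960 in the 2 series. The gene identifiers were not paired with gene names in the files or tables used here, so genes are given by identifier and gene groups are seasonal sets, each chosen on the Control buds of the other series.

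The Control buds set the seasonal reference. Between late summer (July and August) and winter (December and early January), 8258 genes rose and 7844 fell in the deprivation series, and 8273 rose and 8718 fell in the exposure series. Of the 500 genes with the largest winter rise in the exposure series, 334 rose, 5 fell and 161 did not pass the test in the Control buds of the deprivation series, with a median log2 change of 3.18 (camera, adjusted p = 2.57e-28). The corresponding winter-low set had 455 genes that fell and 0 that rose, with a median of -3.27 (adjusted p = 1.25e-46). Across the 26956 genes tested in both series the 2 winter changes had a Pearson correlation of 0.727, and 7.2% of the genes called in both moved in opposite directions; genes are not independent replicates. Between winter and the last sampled Control dates (28 February and 28 March 2019; 16 February and 16 March 2023), 9523 genes rose and 8950 fell in the deprivation series, and 3142 rose and 2912 fell in the exposure series (2803 and 3241 with RLE factors). Of the spring-high genes of the exposure series, 422 rose and 16 fell between winter and spring in the deprivation series (median 2.34, adjusted p = 1.18e-23). The series shared 67 genes between their spring-high sets and 291 between their winter-high sets, where 9.27 were expected for independent lists. The spring count of the exposure series was 1092 without replicate 1, and 2540 without the 4 libraries of a second flow cell. Its spring dates had 2 libraries each and differed: the spring-high level was -0.608 ± 0.016 log2 units on 16 February (SD, n = 2), against -0.662 ± 0.341 on 26 January (SD, n = 3), and 1.782 and 0.400 in the single libraries of 16 March. With 16 March alone as spring 11001 genes were called, and 5241 with 16 February alone, a choice made after seeing the data; the spring sets used in the deprivation series come from both dates.

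The comparison of CC with Control asks how buds of the CC arm departed from the seasonal course. In CC the set of genes that rise in winter Control buds was lower as a whole than in Control. Of the 500 winter-high genes, 203 were lower and 36 higher in CC than in Control over the 8 shared dates, and the others were not called. The median log2 change was -1.15. The mean level of this set lay below Control at 8 of 8 dates, by -1.640 to -0.076 log2 units. The gap was widest on 1 February 2019, when it was 1.05 ± 0.08 log2 units above its late-summer Control level in CC (SD, n = 3) against 2.69 ± 0.13 in Control (SD, n = 3). On 28 February the levels were 1.064 ± 0.164 and 1.266 ± 0.177 (SD, n = 3 each). Of the winter-low genes, 323 were higher and 26 lower, with a median of 1.06. The winter-low level lay above Control at 5 and below it at 3 of the 8 dates. Both sets passed camera, limma's competitive gene set test (adjusted p = 5.34e-10 and 8.12e-09), and both passed with an estimated correlation (adjusted p = 0.00189 for each). The spring-high set was lower (219 genes lower, 112 higher, median -0.39, adjusted p = 0.00376), a call that was lost with an estimated correlation (adjusted p = 0.286). The spring-high level lay below Control at 4 and above it at 4 of the 8 dates, and on 28 March 2019 it was -0.513 ± 0.147 in CC and 1.317 ± 0.008 in Control (SD, n = 3 each). The spring-low set did not pass (adjusted p = 0.204). In all, 9849 genes were higher and 9617 lower in CC among 27313 tested, and 3638 of them changed by at least 1 log2 unit.

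The gene PAV02_REGINAg0134231 was 62.6 ± 42.8 CPM in CC (SD over dates and replicates, n = 24) and 1.86 ± 1.59 CPM in Control (SD, n = 22), a log2 change of 4.88 with a standard error of 0.19 (edgeR quasi-likelihood test, adjusted p = 1.36e-31). Its neighbour in the numbering, PAV02_REGINAg0134241, rose by 4.75. In the other direction PAV03_REGINAg0140141 changed by -4.89 and PAV01_REGINAg0002981 by -4.85, the latter from 99.4 ± 147 CPM in Control to 1.08 ± 1.32 CPM in CC; its call was lost with 1 sequencing lane per library (edgeR, adjusted p = 0.0806, the highest of its 18 alternatives, of which the lowest was 1.73e-54). Whether reads are shared between near-identical neighbouring copies was not checked, since no sequence was used here, so the split between neighbours is uncertain.

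**Figure D1:**
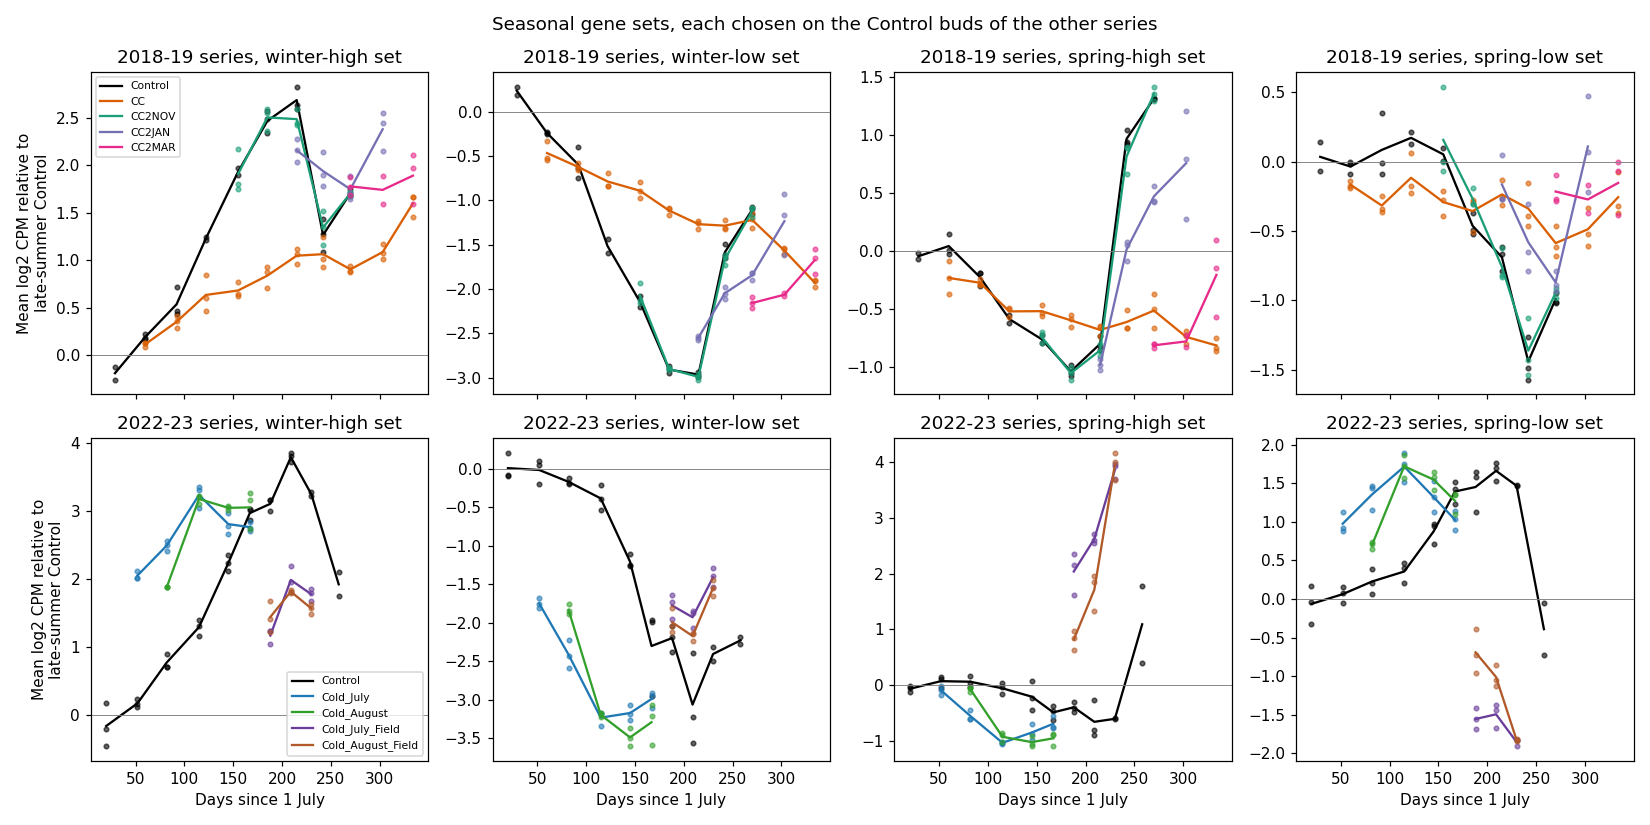
Mean log2 CPM of each seasonal gene set relative to late-summer Control buds of the same series, against days since 1 July. Points are libraries and lines join group means of each arm. The winter-high level of CC on 1 February 2019, the shared date with the widest gap, is 1.05, against 2.69 in Control.

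The difference between CC and Control was not the same early and late in the season. The difference on the 4 dates from 2 January to 28 March 2019 minus the difference on the 3 dates from 30 August to 31 October 2018 was itself different from 0 for 6046 genes in the positive and 6555 in the negative direction (6469 and 6107 with RLE factors). The winter-low set moved up in this contrast (249 genes up, 27 down, median 1.35, adjusted p = 4.06e-11) and the winter-high set moved down (99 down, 38 up, median -0.96, adjusted p = 1.25e-06). The spring-low set moved up (247 up, 33 down, median 1.14, adjusted p = 4.06e-11) and the spring-high set down (179 down, 49 up, median -0.60, adjusted p = 6.14e-05); the spring-high call was lost with an estimated correlation (adjusted p = 0.0976). At single dates edgeR called 6670 genes on 30 August 2018, 7683 on 3 December 2018 and 19632 on 28 March 2019. For 30 August limma-trend, fitted on the compared libraries of that date alone, called 3718.

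**Figure D2:**
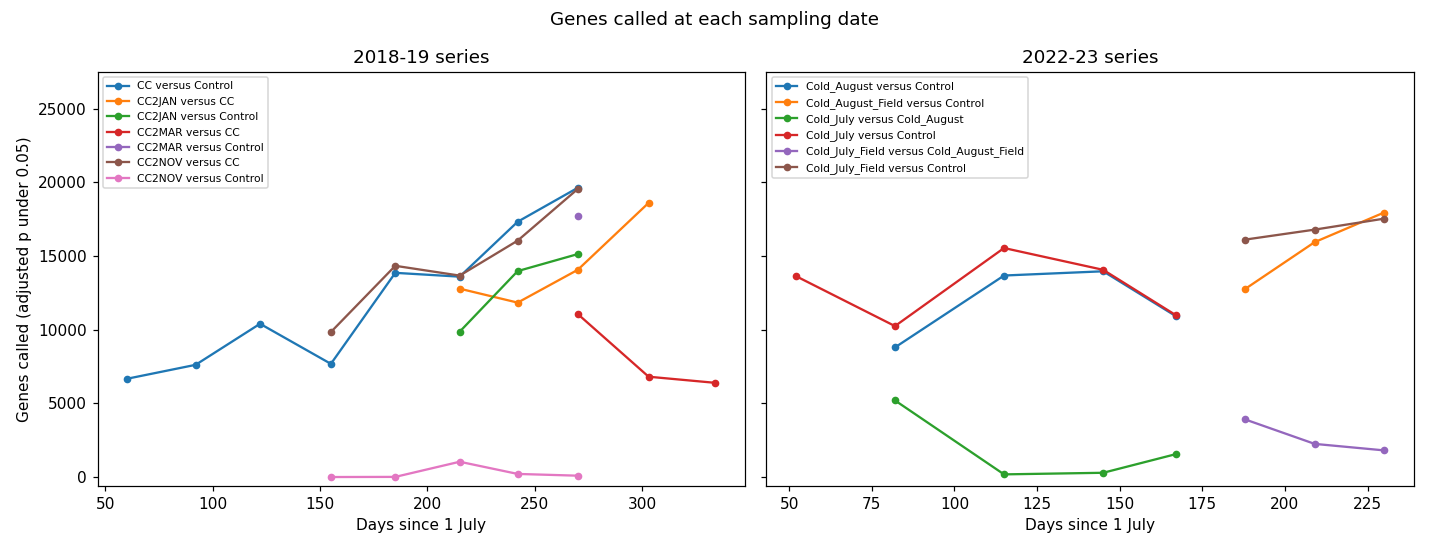
Genes called at adjusted p under 0.05 at each sampling date (days since 1 July) for each pair of arms. CC versus Control ends at 19632 genes, while CC2NOV versus Control peaks at 1039.

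The arms labelled CC2NOV, CC2JAN and CC2MAR are compared with CC and, where dates allow, with Control. CC2NOV buds differed from CC buds in many genes and from Control buds in few. Against CC, 307 winter-high genes were higher and 44 lower (median 1.60), and 343 winter-low genes were lower and 28 higher (median -1.59), with adjusted p = 5.96e-11 and 6.97e-12; both held with an estimated correlation. The spring-high set was higher (246 genes higher, 113 lower, adjusted p = 0.00357) and the spring-low set lower (237 lower, 98 higher, adjusted p = 0.0125), and neither passed with an estimated correlation (adjusted p = 0.283 and 0.321). The winter-low level lay below CC at 4 of the 5 dates and above it on 28 March 2019 (-1.119 ± 0.058 against -1.220 ± 0.085; SD, n = 3 each). Both spring sets changed side within the season: the spring-high level lay below CC at 3 of the 5 dates, with -1.053 ± 0.057 in CC2NOV and -0.597 ± 0.052 in CC on 2 January 2019, and above it at the other 2, with 1.358 ± 0.061 and -0.513 ± 0.147 on 28 March (SD, n = 3 each), and the spring-low level lay above CC at 2 dates and below it at 3. Over all genes, 10267 were higher and 9714 lower than in CC. Against Control, 255 genes were higher and 236 lower, and none of the 4 seasonal sets passed, the lowest adjusted p being 0.0997 for the spring-low set; the winter-high set had a median of 0.10 while its test pointed down. The count of 491 genes was not stable: it was 49, 86 and 137 without replicates 1, 2 and 3, 91 without 2 January, 74 without 1 February, 189 with 1 lane per library, 323 with no filter, 769 with DESeq2 and 914 with the compared groups alone. Per date, edgeR called 1 gene on 3 December 2018 (2114 at an unadjusted p under 0.05, and 8 called by DESeq2), 11 on 2 January, 1039 on 1 February, 212 on 28 February and 93 on 28 March 2019. Fitted on the compared libraries of each date alone, limma-trend called 2, 926, 4 and 0 on the last 4 of these dates. It had 1769 at an unadjusted p under 0.05 on 28 March. The gene of 3 December, named after its values were seen, was PAV01_REGINAg0075151, with 128 ± 3.75 CPM in CC2NOV (SD, n = 3) and 54.6 ± 2.25 CPM in Control (SD, n = 2; log2 change 1.23, edgeR adjusted p = 2.62e-05).

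PAV01_REGINAg0002991 had the largest called rise in CC2NOV against CC, with 65.7 ± 65.6 CPM in CC2NOV (SD over dates and replicates, n = 15) and 0.372 ± 0.49 CPM in CC (SD, n = 15), a log2 change of 6.87 (standard error 0.42, adjusted p = 1.62e-20 by edgeR). PAV02_REGINAg0101131 fell from 29.6 ± 9.99 CPM in CC to 0.925 ± 1.63 CPM in CC2NOV; no fold is given because a group held no read. In CC2JAN against CC the same PAV01_REGINAg0002991 changed by 6.77 (standard error 0.47), and PAV02_REGINAg0134231, the gene that was high in CC, by -5.69 (standard error 0.24).

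CC2JAN buds were higher than CC buds in the winter-high set (313 genes higher, 32 lower, median 1.47, adjusted p = 2.15e-09) and lower in the winter-low set (275 lower, 75 higher, median -0.92, adjusted p = 4.75e-06), and both held with an estimated correlation. Their spring-high set was also higher than in CC (298 higher, 70 lower, adjusted p = 4.75e-06), which did not pass with an estimated correlation (adjusted p = 0.0751). The spring-high and winter-low levels each lay on the other side at 1 of the 4 dates. The spring-high level on 1 February was -0.981 ± 0.047 in CC2JAN and -0.680 ± 0.047 in CC, and the winter-low level on 30 April 2019 was -1.234 ± 0.349 and -1.566 ± 0.037 (SD, n = 3 each), a difference within the spread of the CC2JAN replicates. The spring-low set did not pass (adjusted p = 0.591), with a median of 0.03 while its test pointed down. Against Control on the 3 shared dates, 6791 genes were higher and 6111 lower in CC2JAN (6249 and 6592 with RLE factors); 2080 changed by at least 1 log2 unit, and 5205 did without 1 February. Here the spring-high set was lower (248 genes lower, 31 higher, median -0.64, adjusted p = 5.14e-12, and 0.0167 with an estimated correlation). The spring-low set was higher (195 higher, 41 lower, median 0.58, adjusted p = 1.95e-07), a call lost with an estimated correlation (adjusted p = 0.0739). The winter-low set was lower (91 lower, 61 higher, adjusted p = 0.0212), also lost with an estimated correlation (adjusted p = 0.212). The means of the 2 winter sets are over opposite differences: the winter-low level of CC2JAN was above Control on 1 February (-2.549 ± 0.022 against -2.966 ± 0.031) and below it on 28 February (-2.048 ± 0.071 against -1.586 ± 0.081), and the winter-high level was below Control on 1 February (2.160 ± 0.124 against 2.689 ± 0.126) and above it on 28 February (1.940 ± 0.179 against 1.266 ± 0.177; SD, n = 3 each). The winter-high set did not pass (adjusted p = 0.452), with a median of -0.08 while its test pointed up. The level of the spring-high set on 28 March 2019 was 0.473 ± 0.079 log2 units above late-summer Control in CC2JAN (SD, n = 3) and 1.32 ± 0.01 in Control (SD, n = 3).

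CC2MAR was compared with CC on 28 March and 30 April 2019. As sets, the winter-high genes were higher (193 higher, 13 lower, median 0.85, camera adjusted p = 2.1e-08) and the winter-low genes lower (217 lower, 11 higher, median -0.95, camera adjusted p = 2.95e-10). Both held with an estimated correlation, while the other genes of each set were not called. The spring-high set did not pass (adjusted p = 0.0584), and the spring-low set did (114 higher, 50 lower, adjusted p = 0.0408) but not with an estimated correlation (adjusted p = 0.43). In total 6581 genes were higher and 6157 lower. The count was 8331 when replicate 2 was left out and 6810 without 28 March.

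The cold-exposure series asks how the Cold_July and Cold_August arms differ from Control from August to December. In both arms most genes of the winter-low set were lower than in Control, and most genes of the winter-high set were higher. In Cold_July, 418 of the 500 winter-low genes were lower and 5 higher than in Control (median -2.41, adjusted p = 8.18e-29), and 330 winter-high genes were higher and 65 lower (median 1.46, adjusted p = 1e-19); both held with an estimated correlation. On 22 August the winter-high level was 2.05 ± 0.06 log2 units in Cold_July (SD, n = 3) and 0.167 ± 0.056 in Control (SD, n = 3). By 15 December it was 2.76 ± 0.07 in Cold_July and 2.97 ± 0.09 in Control (SD, n = 3 each). The spring-low set was higher (280 higher, 124 lower, adjusted p = 5.9e-09) and the spring-high set lower (179 lower, 30 higher, adjusted p = 0.0027), and neither passed with an estimated correlation (adjusted p = 0.0729 and 0.295). The spring-low level lay above Control at 4 of the 5 dates and below it on 15 December (1.026 ± 0.125 against 1.394 ± 0.147; SD, n = 3 each). Over 28903 genes tested, 8703 were higher and 10696 lower; at a change of at least 1 log2 unit, 1209 were higher and 4348 lower.

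PAV01_REGINAg0002991 had the largest called rise, from 4.55 ± 6.98 CPM in Control to 310 ± 218 CPM in Cold_July (SD, n = 15 each), a log2 change of 6.95 (standard error 0.39, adjusted p = 2.46e-21 by edgeR). Its neighbour PAV01_REGINAg0002981 rose by 6.22. PAV02_REGINAg0101131 fell from 38.5 ± 33.2 CPM to 0.317 ± 0.617 CPM and PAV01_REGINAg0016101 from 17.2 ± 13.4 CPM to 0.151 ± 0.228 CPM; no fold is given because 1 group of each held no read.

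**Figure D3:**
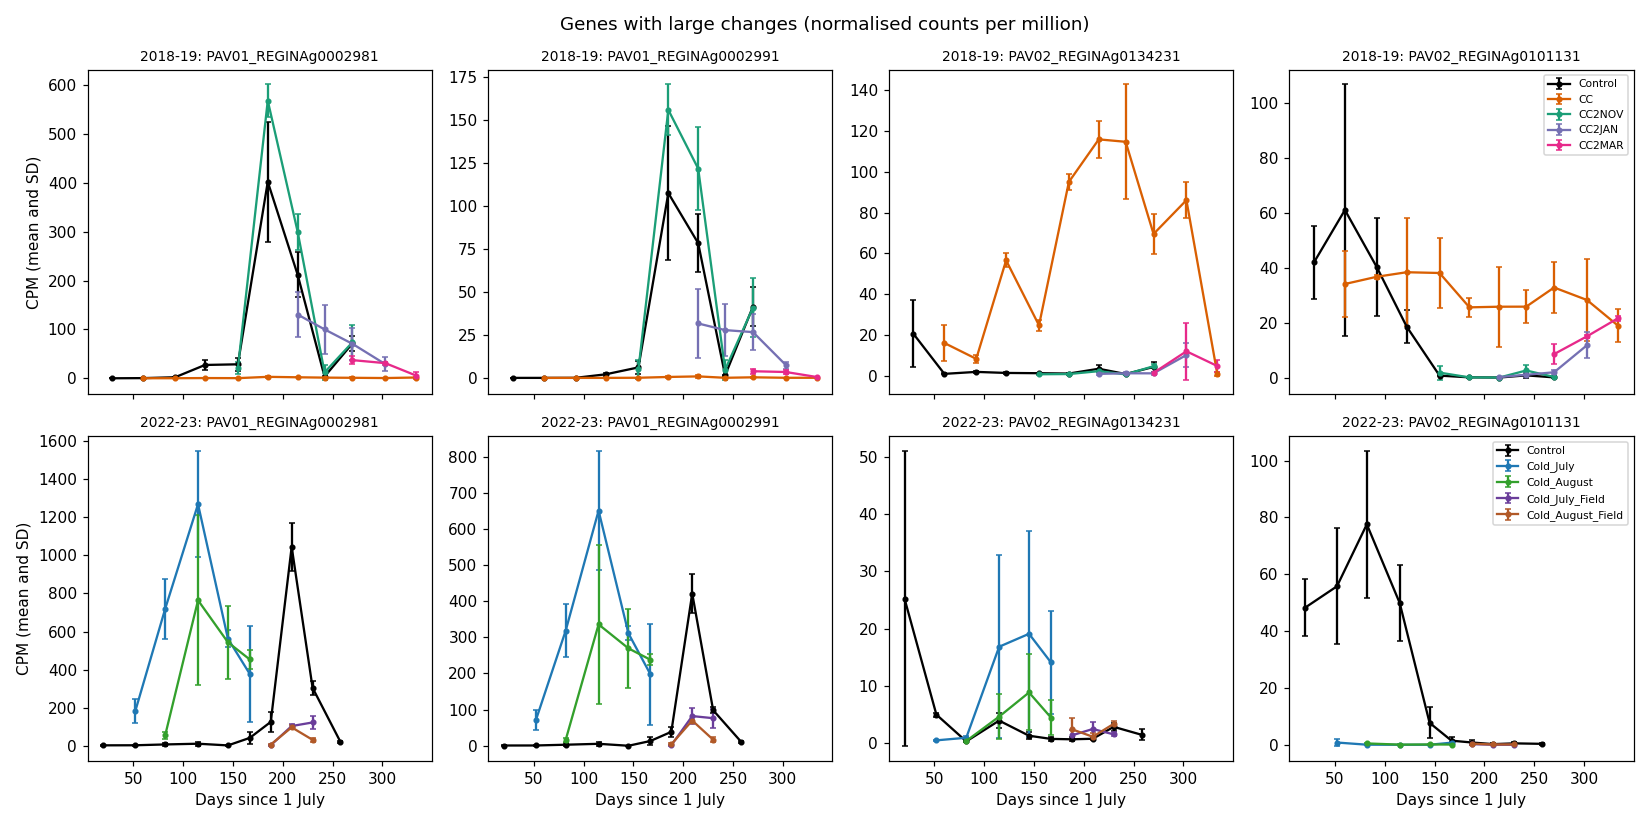
TMM-normalised CPM (group mean and SD, n = 2 or 3) of 4 genes against days since 1 July, with the deprivation arms above and the exposure arms below. PAV01_REGINAg0002991 reaches 650 CPM in Cold_July on 24 October and 421 CPM in Control on 26 January 2023.

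In Cold_August against Control, 416 winter-low genes were lower and 3 higher (median -2.60, adjusted p = 2.14e-31), and 303 winter-high genes were higher and 47 lower (median 1.08, adjusted p = 2.8e-18), passing also with an estimated correlation. In all, 7937 genes were higher and 9772 lower. The spring-low set (261 higher, 98 lower, adjusted p = 3.7e-09) and the spring-high set (175 lower, 15 higher, adjusted p = 0.00095) passed, and neither did with an estimated correlation (adjusted p = 0.069 and 0.249). The spring-low level lay above Control at 3 of the 4 dates and below it on 15 December, by less than the SD (1.272 ± 0.145 against 1.394 ± 0.147; SD, n = 3 each). Set directly against each other, Cold_July and Cold_August differed in 1916 genes higher and 2243 lower in Cold_July, and none of the 4 seasonal sets passed over the mean of the dates (lowest adjusted p = 0.683). Levels at single dates differed in opposite directions, which a mean cancels: on 21 September the winter-high level was 2.491 ± 0.074 in Cold_July and 1.878 ± 0.002 in Cold_August and the winter-low level -2.412 ± 0.179 and -1.832 ± 0.067, while on 23 November the winter-high level was 2.807 ± 0.155 and 3.046 ± 0.032 and the winter-low level -3.174 ± 0.101 and -3.491 ± 0.120 (SD, n = 3 each). At single dates 5200 genes were called on 21 September, 182 on 24 October, 290 on 23 November and 1556 on 15 December by edgeR. On these dates DESeq2 called 5882, 414, 450 and 2149. Fitted on the compared libraries of each date alone, limma-trend called 6411, 1, 40 and 0, with 1841 at an unadjusted p under 0.05 on 15 December. The count of 4159 was 1691, 1236 and 1851 without replicates 1, 2 and 3, 2575 with the compared groups alone, 2310 without 21 September and 2741 without 24 October.

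From 5 January to 16 February 2023 the arms labelled Cold_July_Field and Cold_August_Field were compared with Control. In both arms most genes of the spring-high set were higher and most genes of the spring-low set were lower. In Cold_July_Field, 436 of the 500 spring-high genes were higher and 6 lower (median 4.81, adjusted p = 3.37e-33), and 489 spring-low genes were lower and 0 higher (median -3.50, adjusted p = 7.99e-50). In Cold_August_Field, 380 spring-high genes were higher and 16 lower (median 3.82, adjusted p = 2.32e-29), and 478 spring-low genes were lower and 1 higher (median -2.97, adjusted p = 1.02e-47). Winter-high genes were lower in both arms (356 and 359 genes lower, 65 and 54 higher, median -1.99 and -2.12, adjusted p = 1.86e-15 and 5.91e-19). These sets passed with an estimated correlation. The winter-low set was higher in both arms (227 and 221 genes higher, 121 and 117 lower, adjusted p = 0.00306 and 0.00713) and was lost with an estimated correlation (adjusted p = 0.241 and 0.286). Over all genes, 10937 were higher and 10412 lower in Cold_July_Field, and 10480 higher and 10005 lower in Cold_August_Field. PAV06_REGINAg0306311 was 29.0 ± 12.5 CPM in Cold_July_Field (SD, n = 9) and 0.0156 ± 0.0441 CPM in Control (SD, n = 8), and PAV06_REGINAg0288451 had no read in the 9 Cold_July_Field libraries and 16.2 ± 11.9 CPM in Control (SD, n = 8). A total of 3 counts over those 9 libraries would be 0.0113 CPM, so it was at least 1429-fold lower, a bound that covers counting error only.

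Cold_July_Field and Cold_August_Field differed from each other in 2908 genes higher and 2216 lower in Cold_July_Field. The spring-high set was higher (180 higher, 3 lower, median 0.88, adjusted p = 2.48e-19) and the spring-low set lower (170 lower, 10 higher, median -0.58, adjusted p = 9.08e-20), and both held with an estimated correlation (adjusted p = 0.00637 for each). The winter-low set was higher (71 higher, 20 lower, adjusted p = 0.023), which did not hold with an estimated correlation (adjusted p = 0.46). The winter-high set did not pass (adjusted p = 0.705), with a median of 0.05 while its test pointed down. On 5 January 2023 the spring-high level was 2.04 ± 0.38 log2 units in Cold_July_Field and 0.816 ± 0.177 in Cold_August_Field, and on 16 February it was 3.86 ± 0.15 and 3.96 ± 0.24 (SD, n = 3 each). The count of 5124 was 1989, 3251 and 3198 without replicates 1, 2 and 3, and 3374 without 26 January.

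Each group was also placed on the Control dates of the other series by its highest Spearman correlation over 2000 genes, a description with no test. Control buds of 2 January 2019 lay closest to 26 January 2023 (0.861), and CC2NOV buds of the same date to that date as well (0.864). Cold_July buds of 22 August and 21 September lay closest to Control of 31 October and 3 December 2018 (0.588 and 0.677), 70 and 73 days later in the season. Cold_July_Field and Cold_August_Field of 5 January 2023 both lay closest to Control of 28 February 2019 (0.870 and 0.817), 54 days later. CC2JAN of 1 February 2019 lay closest to 15 December (0.814), 48 days earlier. For CC the highest correlation stayed between 0.229 and 0.376 from 31 October 2018 to 30 April 2019. Autumn Control buds had low values as well, with 0.336 on 1 October 2018 and 0.253 on 24 October of the exposure series. Placed on the Control dates of its own series, without centring, CC lay closest to 1 October 2018 on each of the 8 dates to 28 March 2019, with correlations from 0.955 on 30 August 2018 to 0.823 on 28 March, when 3 December was next at 0.820. On 30 April and 31 May 2019 it lay closest to 3 December (0.808 and 0.831). This reference was chosen after seeing the data. Without centring each series on its own Control buds, 23 of the 37 treated groups had the same closest date.

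**Figure D4:**
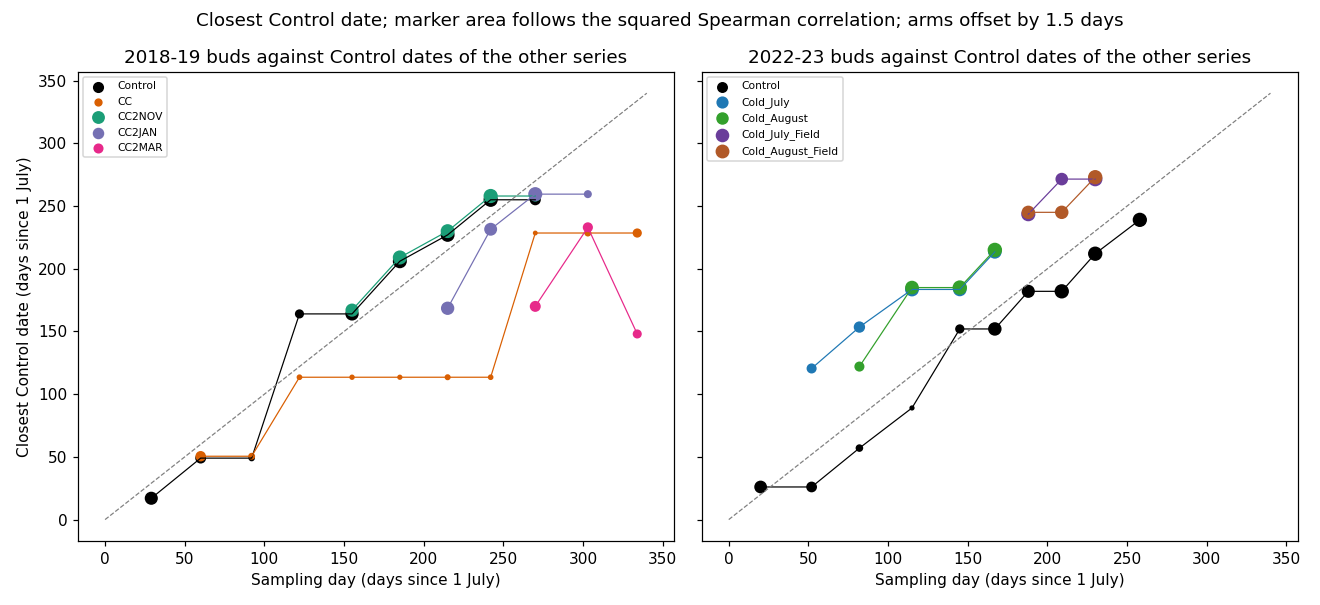
Closest Control date of the other series against sampling day, both as days since 1 July. Marker area follows the squared Spearman correlation, lines join the dates of an arm, and the dashed line marks equal days; CC markers are small, with correlations of 0.229 to 0.376 between 31 October 2018 and 30 April 2019.

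Finally the changes of the deprivation and exposure series, which share no library, were set side by side. Over 26956 genes the log2 changes of CC versus Control and Cold_July versus Control had a Pearson correlation of -0.307 and a Spearman correlation of -0.240. Of the genes called in both, 8985 moved in opposite directions, which is 64.6%. Among changes of at least 1 log2 unit in both the share was 80.4%, mostly through genes higher in CC. Of those, 911 were lower and 38 higher in Cold_July, where 282.5 and 73.16 were expected for independent calls. Of the genes lower in CC, 311 were higher and 259 lower in Cold_July, where 60.4 and 233.2 were expected. For Cold_August the share was 61.8%, and 79.6% at 1 log2 unit. There 853 of the genes higher in CC were lower and 37 higher in Cold_August, where 266.8 and 57.75 were expected. Of the genes lower in CC, 254 were higher and 247 lower, where 47.68 and 220.3 were expected. For Cold_July_Field, over other dates, the opposite share was 68.9%. The Cold_July change correlated with the Control winter change of the deprivation series (Pearson 0.637), with 8.0% of shared calls opposite. The Cold_July_Field change correlated with the Control spring change of the deprivation series (Pearson 0.807), with 3.9% opposite. These correlations are across genes, which are not independent replicates.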

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

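The tests of read and library number on 3 December, the comparison of the falling genes with the winter change and the dates of the 2 differences between single dates were chosen only after the results were seen.

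The differences between arms were not constant over dates. CC minus Control changed between the early and the late dates for 12601 genes. The difference between Cold_July and Cold_August on 21 September differed from that on 23 November for 2655 genes. The difference between CC2NOV and Control on 1 February 2019 differed from that on 28 March for 112 genes.

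The CC2NOV and Control buds of 3 December 2018 differed in 1 called gene. A library deposited under both labels is argued against. The lowest chi-square per degree of freedom between a CC2NOV and a Control library of 1 date was 2.72. Replicates of these arms on the 5 shared dates, measured the same way, gave at least 2.23. Lanes of a library gave at most 1.45, but at lower depth and with another read cut-off. Too few reads or libraries stays open: the 95% interval of the difference lay within 1 log2 unit of 0 for 67.7% of genes, and of the 490 genes called over the other 4 dates 63.7% had the same direction on 3 December, between the bounds set for either answer. The interval was derived from the change and its test statistic. Genes with hardly any reads in both arms can therefore count as within it, and 67.7% may be too high. The same 2 Control libraries gave 7683 calls against CC on that date, which speaks for power to call changes of the size seen there but not smaller ones. An exchange of CC2NOV and Control libraries cannot be told apart from likeness of the arms: 23 of 29 libraries over the 5 dates lay nearest to their own arm, but 1 of 5 on 3 December; a similar state of the buds in both arms stays open as an untested hypothesis.

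Among changes of at least 1 log2 unit in Cold_July against Control, 78.2% were falls. After the median change of all genes was set to 0, 75.5% were falls. The median removed was -0.058 log2 units, too small to move the share far, so this step cannot decide on scaling. A few genes taking most of the counts are argued against, as the 10 highest took 1.56 percentage points more of the counts in Cold_July. Depth is argued against, as Control libraries were on average 1.04 times as deep. Of the 3850 falling genes also measured in the deprivation series, 67.5% were called lower in winter than in late summer in its Control buds, against 29.1% of all genes measured in both. An earlier winter decline in Cold_July may be the source, as a hypothesis found on the same data.

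The 2 Control libraries of 16 March 2023 lay at 0.693 and 1.363 mean log2 CPM in the spring-low set. Second minus first flow cell was -0.670 on 16 March. In the 3 other groups with libraries from both flow cells it was 0.050, 0.015 and 0.176, the lowest ratio to the March difference being -0.26. A constant flow cell shift of the March size is argued against. Each value rests on 1 library of the second flow cell, and the small differences do not show an opposite effect. Their depths were 16.88 and 22.78 M. After the deeper library was thinned to the depth of the other, 98.3% of the difference was left. The levels are already scaled to depth and the depths were close. Thinning could therefore hardly change the difference, so it cannot decide on depth. No biological explanation was tested.

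Other splits of the libraries were tested with limma-trend, which gives other counts than edgeR, exchanging libraries within dates (for the Control seasons, among the compared groups). In each of the 17 comparisons the real split was the 1 of 100 with the most genes. This argues against a chance division of these libraries. A difference between trees is not excluded, since the labels do not say whether replicates came from separate trees. For late minus early the splits also remove any constant difference between CC and Control, so they do not test the change over the season alone. The real count and the highest other were 21056 and 8588 for CC versus Control, 14760 and 6993 for its late minus early dates, 21251 and 5495 for CC2NOV versus CC, 1230 and 70 for CC2NOV versus Control, 19361 and 11697 for CC2JAN versus CC, 13463 and 6259 for CC2JAN versus Control, and 13502 and 8797 for CC2MAR versus CC. They were 19718 and 9463 for Cold_July versus Control, 16582 and 7371 for Cold_August versus Control, 2418 and 107 for Cold_July versus Cold_August, 21436 and 17302 for Cold_July_Field versus Control, 20097 and 13321 for Cold_August_Field versus Control, and 7568 and 4899 between the Field arms. For the Control seasons they were 15997 and 11884 (winter) and 19055 and 11288 (spring) in the deprivation series, and 16461 and 6 (winter) and 4336 and 3203 (spring) in the exposure series. At single dates, 3 libraries against 3 allow 10 splits, too few for a share under 0.05. There the real counts were 3718 to 19810 for CC versus Control with a highest other of 6, and 0 to 926 for CC2NOV versus Control with a highest other of 11; on 28 March 2019 all 10 splits called as many as the real 0 (1769 genes at an unadjusted p under 0.05; edgeR called 93). For Cold_July versus Cold_August they were 0 to 6411, with a highest other of 0, and all 10 splits as high as the real 0 on 15 December (1841 at an unadjusted p under 0.05; edgeR called 1556). The real counts were 7959 to 19724 for CC2NOV versus CC, 9257 to 14554 for CC2JAN versus CC and 4697 to 15202 for CC2JAN versus Control. For CC2MAR they were 10693 against CC on 28 March and 17560 against Control. On 31 May 2019, where arm and flow cell cannot be told apart, the count for CC2MAR versus CC was 407 (edgeR called 6395). The real counts were 6177 to 15640 for Cold_July and 3452 to 12453 for Cold_August versus Control. They were 14313 to 15063 for Cold_July_Field and 10299 to 13559 for Cold_August_Field versus Control, and 1107 to 4051 between the Field arms. The highest other in these was 1, in CC2JAN and in CC2MAR versus CC, and 0 in the remaining pairs.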

How the results depend on the processing

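The uncentred and same-series closest dates, the fits without the second flow cells, the single spring dates of the exposure series, and fry and RLE for the seasonal sets were chosen after seeing the data. Of the alternatives for the comparison counts and their summaries, 206 stayed within the bound set for them and 45 moved beyond it. The bound was 1.5 times the main value. For the opposite shares of CC against Cold_July and Cold_August it was instead a binomial confidence interval over genes around the main share. The cause was not tested except where fewer genes, libraries or dates enter by construction. For the counts at single dates and the 2 differences between dates, 400 stayed within 1.5 times and 111 moved beyond it. With RLE factors the larger of the higher and lower counts changed side for CC versus Control (49.7% higher), its late minus early dates (51.4%), CC2JAN (48.7%) and CC2NOV (45.0%) versus Control, CC2MAR versus CC (49.2%), and Control winter of the deprivation (47.9%) and spring of the exposure series (46.4%). No named gene reversed under any alternative: 826 values kept their call and 50 lost it. The naming rule takes called genes with the largest changes and, between arms, the same sign at every averaged date. A lack of reversals is therefore favoured by the choice and says little about other genes. For the seasonal sets 315 tests kept their side of the threshold, 19 lost the call and 6 gained it; of 52 set tests between arms, 39 passed with the preset correlation and 24 with an estimated correlation.

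Requiring at least 1 log2 unit left 3638 genes for CC versus Control, 3805 for late minus early, 5370 for CC2NOV versus CC, 26 for CC2NOV versus Control, 5261 for CC2JAN versus CC, 2080 for CC2JAN versus Control, 2768 for CC2MAR versus CC, 5557 for Cold_July and 5090 for Cold_August versus Control, 455 between them, 9595 for Cold_July_Field and 8411 for Cold_August_Field versus Control, and 978 between them. For the Control seasons it left 5911 (winter) and 7583 (spring) in the deprivation series, and 6768 and 1580 in the exposure series. It raised the opposite share of CC against Cold_July to 80.4% and against Cold_August to 79.6%, where most of the opposite genes were higher in CC.

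CC2NOV versus Control moved most, from 491 genes to 914 with the compared groups only, 769 with DESeq2, 323 with no filter, 189 with the first lane only, 91 without 2 January and 74 without 1 February 2019, and to 49 to 137 with a replicate left out; it was 663 without 28 March and 490 without 3 December 2018. A single lane or a left-out replicate or date enters fewer reads or libraries by construction; the cause of the other shifts was not tested. Cold_July versus Cold_August went from 4159 to 2575 with the compared groups only, 2310 without 21 September, 2741 without 24 October, and 1236 to 1851 with a replicate left out. Cold_July_Field versus Cold_August_Field went from 5124 to 3374 without 26 January and to 1989 to 3251 with a replicate left out. CC2MAR versus CC went to 6810 without 28 March and 8331 to 11252 with a replicate left out. The Control spring change of the exposure series went to 11001 without 16 February, 2540 without the second flow cell and 1092 to 4743 with a replicate left out. The closest date was the same for 27 of 37 groups with 500 genes, 34 with 5000, 36 with Pearson and 23 when not centred; on same-series Control dates the 5 CC2NOV groups lay closest to their own dates (0.924 to 0.976).

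Replicate numbers showed no clear pairing of the samples: deviations of same-numbered libraries of a date correlated between -0.252 and 0.224 in the deprivation series and between -0.231 and 0.310 in the exposure series, and 27 of 86 and 29 of 68 libraries correlated best with their own number. Mean correlations for the same and for other numbers were -0.001 and 0.000 in the deprivation series, and 0.018 and -0.009 in the exposure series. A weak pairing in the exposure series is not excluded. With a replicate block, 515 genes were called for CC2NOV versus Control and 19451 for CC versus Control, and no count of a comparison moved by more than 1.5 times. Gene lists by function were not run, since no identifier was paired with a name.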

Other observations

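The test of neighbouring genes and the counts outside the Control range were chosen only after the data were seen.

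Some genes left the range of the Control dates altogether. A gene was counted when its group mean lay more than 1 log2 unit above the highest or below the lowest Control date of its series. CC went from 37 such genes on 30 August 2018 to 432 on 28 March and 699 on 30 April 2019, and had 437 on 31 May, when it was sequenced on flow cells of its own, while CC2NOV, measured the same way, had 6 on 3 December 2018 and 107 on 28 March 2019. The last Control date used here was 28 March 2019, so later groups are compared with earlier Control dates. CC2JAN had 5 on 28 March and 834 on 30 April 2019, 760 of them above the range. Its libraries of 30 April were unlike each other, with the lowest replicate correlation of the deprivation series (Spearman 0.963), so that count rests on a mean of unlike libraries. In the exposure series, Cold_July had 440 genes below and 115 above the range on 15 December, and Cold_August 539 below and 59 above. Cold_July_Field had 2028 genes above and 822 below on 16 February 2023, and Cold_August_Field 1838 and 806; the last Control date there was 16 March.

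As a hypothesis, genes that follow each other in the numbering of a chromosome may change alike. The mean product of the standardised log2 changes of adjacent genes was 0.240 for CC versus Control, against at most 0.022 in 1000 shuffled orders within chromosomes. It was 0.306 for Cold_July versus Control (at most 0.023) and 0.235 for Cold_July_Field versus Control (at most 0.019). Neighbouring genes may respond together, and near-identical copies that share reads could give the same value; sequences were not used here, so these were not separated.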
